A study of Mus musculus with 6 samples.

How the data were processed

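Cells of 3 libraries of mouse mammary cells were compared, made with the Adeno-K5-Cre virus from control, Pik3caHR and Pik3caHR Kdm6aKO mice. Groups were taken from the titles and genotypes in the labels. The 3 libraries made with the Adeno-Cre virus were not analysed here. Per the labels' protocols, glands were digested, cells were sorted for GFP and libraries followed the 10x Genomics protocol. The deposited files hold raw counts of UMIs per gene and barcode, one matrix per library, and per the submitters' processing notes the tools were Cell Ranger, Cell Ranger ATAC and Seurat with the build mm10. Their versions and roles are not given in the sources used here, and neither is the annotation. The matrices held 31053 genes, of which 30934 matched GENCODE vM21 (mm10) by identifier, which gave coordinates. They hold no EGFP or Cas9 entry.

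Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 19471 of 22420. Scrublet, in scanpy 1.11.5, was run per library with an expected rate of 0.06 and marked 163 (2.28%), 28 (0.642%) and 4 (0.0447%) barcodes in the control, Pik3caHR and Kdm6aKO libraries. Under a rule fixed in advance, nothing was removed where it marked under 0.5%, which was the Kdm6aKO library. Of the barcodes that passed the filters, 156 and 25 were removed from the control and Pik3caHR libraries, which left 19290. Counts per 10000 were log-transformed, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was clustered with leidenalg 0.10.2 at resolution 1.0, without integration. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.

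A cluster took the class with most markers among its 10 leading genes by fold, from 17 marker lists fixed before the data were examined, with at least 3 markers detected. A luminal or basal name was dropped for mixed-keratin where the other keratins had more RNA, a rule chosen after seeing the data. It applied to 1 cluster, in which Krt5, Krt14 and Krt17 summed to 3260 and Krt8, Krt18 and Krt19 to 1163 CPM. Cluster 13 was named cycling, with 5 of its own markers and 2 alveolar ones among its leading genes. Cluster 12, basal-like, had a median of 1259 UMIs per cell, and 9 of its 10 leading genes were basal markers. The names of clusters 7, 11 and 20 (basal-like, macrophage-like and pericyte-like) rest on 1 marker each among the leading genes. Class shares carry exact Clopper-Pearson 95% intervals.

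UMIs were summed over the cells of a class in each library. The log2 ratio of CPM, UMIs scaled to the total of the class, was taken with 0.5 count added, and its exact conditional binomial interval covers counting error only. With 1 library per genotype no test was made. The basal-like sums were 55996166, 50422407 and 66245906 UMIs in 4446, 2925 and 5686 cells. A gene at 0 was given a bound of 3 counts per library. Of the 32 gene lists fixed in advance, members with at least 20 UMIs over both libraries were counted as higher or lower at a log2 ratio of 0.58 (1.5-fold) or more in size. The list's median was ranked among 10000 random lists of equal size matched on expression in 20 bins, as a description of these libraries. Lists with a median of at least 0.3 in size or a percentile under 2.5 or over 97.5 were described, and always the milk, luminal progenitor, hormone-sensing, pan-luminal, basal identity and contractile lists.

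Single genes were named by a rule fixed in advance: among genes with at least 100 UMIs and a log2 ratio of at least 1 in size, the 10 highest and 10 lowest of each main comparison and the 5 highest and 5 lowest of the third, leaving out mitochondrial, ribosomal and haemoglobin genes and symbols that start with Gm and a digit or end in Rik. For described lists the members with the 2 highest and 2 lowest ratios could be named, and any member of the milk and luminal progenitor lists. For shares of cells with a UMI, each cell was thinned to 3000 UMIs, which left out 168, 122 and 306 basal-like and 302, 128 and 636 non-epithelial cells of the control, Pik3caHR and Kdm6aKO libraries. Non-epithelial cells of the same library gave the background.

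The steps were tested on simulated data with 200 changed genes drawn on the real basal-like sums. For Pik3caHR over control, over 14565 genes, 99.0% of the measured genes changed 2-fold and 100% of those changed 4-fold passed the 1.5-fold limit on the right side, as did 3.60% of unchanged genes. For Kdm6aKO over Pik3caHR, over 14781 genes, the shares were 96.9%, 100% and 3.48%. The simulated counts held counting error only, with no variation between cells, mice or libraries. These shares therefore do not give the rate of false calls between libraries. Alternatives were fixed before the data were examined, among them other filters, resolutions, depths and scaling by edgeR 4.0.16 TMM factors in R 4.3.3. Others were chosen after seeing the data: removing the 6% of cells with the highest Scrublet scores, adding the mixed-keratin cluster to basal-like cells, and leaving out the low-depth or the interferon-led basal-like cluster. The interferon, MHC class II and immediate early counts joined the counts followed across alternatives after their values were seen.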

Results

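Single-cell RNA sequencing was used to compare mouse mammary cells that carried different alleles in the cells reached by a Cre virus. The labels describe 6 libraries, and the 3 made with the Adeno-Cre virus were not analysed here. The other 3 were made with the Adeno-K5-Cre virus, which the labels call enriched for basal cells. Each came from glands harvested 2 weeks after the virus, with 2 glands pooled per mouse, and from cells sorted for green fluorescence. The control library carried a Cre-dependent Cas9-EGFP reporter. The Pik3caHR library carried in addition a Cre-dependent Pik3ca allele with the H1047R change, an activating change in the catalytic subunit of phosphoinositide 3-kinase. The Kdm6aKO library carried both of these and floxed Kdm6a, the gene of an X-linked histone H3 lysine 27 demethylase. Each genotype had 1 library, so no difference below has a replicate check, a test or a p-value, and all intervals are exact 95% intervals that cover counting error only.

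The control library held 7860 barcodes and 81067859 UMIs, the Pik3caHR library 4846 barcodes and 75862824 UMIs, and the Kdm6aKO library 9714 barcodes and 99645970 UMIs. After filtering, 6573, 4101 and 8616 cells remained, with medians of 11332, 16513 and 11004 UMIs per cell. Clustering the 3 libraries together gave 21 clusters. Basal-like cells, which carried Krt5, Krt14 and contractile genes, made up 67.6% (66.5 to 68.8) of the control library, 71.3% (69.9 to 72.7) of the Pik3caHR library and 66.0% (65.0 to 67.0) of the Kdm6aKO library. Ratios of these basal-like shares moved with the clustering resolution by more than the counting intervals, as given below under the processing. The libraries filled different basal-like clusters: clusters 0 and 7 held most of these cells in the control library, clusters 3 and 5 in the Pik3caHR library and clusters 1, 2 and 4 in the Kdm6aKO library. Cluster 7, of which 1031 cells came from the control library, was led by interferon-induced genes. Macrophage-like cells were present despite the sort for green fluorescence, at 26.1% (25.1 to 27.2), 13.1% (12.03 to 14.1) and 11.3% (10.7 to 12.02) of the control, Pik3caHR and Kdm6aKO libraries. The sort can set all of these shares. Macrophage-like cells filled different clusters too: cluster 6 held 890, 149 and 110 cells of the control, Pik3caHR and Kdm6aKO libraries. Cluster 8 held 146, 275 and 580. Ratios in macrophages can therefore reflect a different mix of these clusters.

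Pik3ca (ENSMUSG00000027665, mm10 chromosome 3, 32397671 to 32468486) was counted at 33.2 CPM (31.7 to 34.7), the unit for UMIs scaled to the total of the class, in control basal-like cells, at 74.0 (71.6 to 76.4) in the Pik3caHR library and at 70.9 (68.9 to 73.0) in the Kdm6aKO library. Kdm6a (ENSMUSG00000037369, mm10 chromosome X, 18162575 to 18279936) was counted at 22.1 (20.8 to 23.3), 27.03 (25.6 to 28.5) and 19.3 (18.3 to 20.4) CPM. The log2 ratio of the Kdm6aKO library to the Pik3caHR library was -0.48 (-0.60 to -0.37) for Kdm6a. It was -0.46 (-0.79 to -0.12) in alveolar-like and -0.54 (-0.95 to -0.14) in cycling cells. In hormone-sensing-like cells it was -0.27 (-0.89 to 0.30) and in macrophages -0.04 (-0.35 to 0.27). Macrophages of the control, Pik3caHR and Kdm6aKO libraries held Pik3ca at 29.7, 34.2 and 61.3 CPM, so its higher counts were not confined to epithelial cells. Which exons the floxed allele loses is not given in the sources used here, so counts of Kdm6a may come from outside the deleted part and then do not check the label. Whether reads of the H1047R allele count towards Pik3ca is not given either.

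The first comparison asked how basal cells and their neighbours differed where mutant Pik3ca was present. The Pik3caHR library held 8.70 times (6.35 to 12.1) the control share of luminal alveolar-like cells, marked by milk protein genes, at 6.22% (5.50 to 7.001) against 0.715% (0.526 to 0.9497). Luminal hormone-sensing-like cells, marked by Prlr and Cited1, were 4.01 times (3.06 to 5.30) the control share, at 4.63% (4.01 to 5.32) against 1.16% (0.912 to 1.44). Cells of the cycling cluster were 14.2 times (7.78 to 28.3) the control share, at 2.59% against 0.183%. Within basal-like cells, milk genes were higher, some of them not told apart from free RNA, and interferon-induced and antigen presentation genes lower, than in the control library. With the milk and luminal progenitor lists left out of the clustering, the alveolar-like ratio was 7.30, at Leiden resolution 0.5 it was 5.50, and with each library clustered alone the cycling ratio was 6.32.

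**Figure D1:**
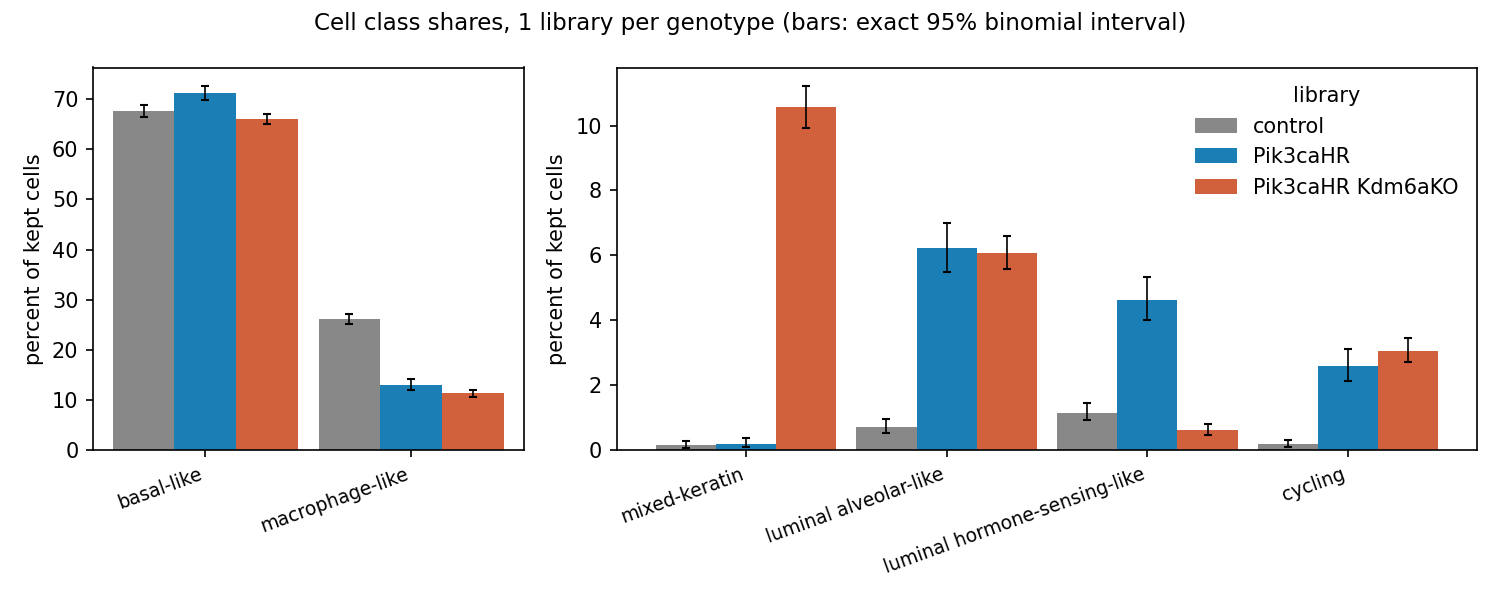
Percent of kept cells in each cell class (y axis) for the control, Pik3caHR and Pik3caHR Kdm6aKO libraries, with 1 library per genotype and exact 95% binomial intervals as error bars. The alveolar-like share was 0.715%, 6.22% and 6.08%, and the mixed-keratin share 0.152%, 0.195% and 10.6%.

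Among 16 measured genes of the milk and alveolar secretory list, 13 were at least 1.5-fold higher in Pik3caHR than in control basal-like cells and 3 were lower (median log2 ratio 1.82). Only 8 were higher after thinning to 3000 UMIs (median 1.53), and 8 with members of at least 100 UMIs (median 1.62). Both settings leave out members with few UMIs, so these counts are not out of 16 and part of the fall may be lost members. Its percentile among 10000 random lists matched on expression was 100. Csn1s1 and Csn2, which encode caseins, had 0 UMIs in control basal-like cells and were at least 16.7-fold and 10.4-fold higher in the Pik3caHR library. Csn3, which encodes kappa-casein (ENSMUSG00000001622, chromosome 5, 87925579 to 87932665), was at 157 against 10.7 CPM, a log2 ratio of 3.87 (3.75 to 3.99). Muc15 and Cidea were lower, with log2 ratios of -1.54 (-1.73 to -1.36) and -2.09 (-3.29 to -1.14). Free RNA also gives such counts. After thinning to 3000 UMIs, Csn3 was seen in 13.7% (12.5 to 15.03) of Pik3caHR basal-like cells and in 4.29% (2.68 to 6.49) of non-epithelial cells of that library, against 1.82% (1.44 to 2.27) and 0.119% (0.0144 to 0.429) in control. Median depths were 17017 and 6626 UMIs for basal-like and non-epithelial cells of the Pik3caHR library and 12255 and 7502 in control. Without thinning, the Csn3 shares in basal-like cells were 32.5% and 5.24%. The Wfdc18 share in Pik3caHR basal-like cells, 6.96% (6.04 to 7.96), was at equal depth within the interval of the non-epithelial cells, 6.95% (4.86 to 9.58). Csn2 and Csn1s1 were seen in only 3 and 9 of 2803 basal-like and 1 and 2 of 489 non-epithelial cells. Without thinning, the deeper basal-like cells had more: 18.2% against 14.1% for Wfdc18, 0.923% against 0.810% for Csn2 and 1.16% against 0.648% for Csn1s1. For these 3 genes free RNA was not told apart from expression.

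Other luminal lists were split. Of 14 luminal progenitor genes, 6 were higher and 1 lower (median 0.19, percentile 91.8), among them Ehf, an ETS-family factor, at 2.89 (2.42 to 3.43), and Elf5, a regulator of alveolar fate, at 2.02 (1.05 to 3.25). Elf5 was at only 0.754 CPM in Pik3caHR basal-like cells. After thinning it was seen in 5 of 2803 basal-like and 0 of 489 non-epithelial cells, too few to tell free RNA apart from expression. Shares of cells with a UMI were not taken for Ehf. Of 14 hormone-sensing genes, 4 were higher and 3 lower (median 0.34), and 2 were higher after thinning, with Areg, an EGF receptor ligand, at 1.09 (1.02 to 1.15) and Tbx3 at -1.35 (-1.47 to -1.24). Pan-luminal genes went the other way: 9 of 16 were lower and 1 higher (median -0.67), including the luminal keratin gene Krt18, at 152 against 753 CPM, and Cldn7 at -2.62 (-2.92 to -2.33). Over all kept cells, where alveolar-like and hormone-sensing-like cells count too, the pan-luminal median was 1.17. The share of basal-like cells with both a basal keratin (Krt5 or Krt14) and a luminal keratin (Krt8 or Krt18) was 86.2% (84.9 to 87.4) against 97.2% (96.7 to 97.7) in control, and 3.88% and 2.98% in non-epithelial cells.

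Basal and matrix lists had more members higher than lower, with most within 1.5-fold. Of 18 basal identity genes, 4 were higher and 1 lower (median 0.27), with Nrg1, which encodes neuregulin 1, at 1.98 (1.95 to 2.01) and Id4 at -1.12 (-1.16 to -1.08). Of 19 contractile genes, 4 were higher and 0 lower (median 0.26), and 2 were higher at Leiden resolution 2.0. Of 19 basement membrane and adhesion genes, 8 were higher and 0 lower (median 0.46), with the laminin gene Lama1 at 1.78 (1.63 to 1.93) and the nidogen gene Nid1 at 1.76 (1.64 to 1.88). Immediate early genes had 10 of 19 members higher and 0 lower (median 0.58), led by Btg2 at 1.47 (1.38 to 1.56), and 6 were higher without the interferon-led cluster. Proliferation genes had 11 of 22 higher and 3 lower (median 0.58), although cycling cells formed a cluster of their own. Cholesterol synthesis genes had 4 of 22 higher and 0 lower (median 0.42), fatty acid synthesis genes 8 of 18 higher and 1 lower (median 0.31). Amino acid and ATF4 response genes had 2 of 20 higher and 1 lower (median 0.28), cell cycle inhibition genes 4 of 14 higher and 0 lower (median 0.32), and oxidative phosphorylation genes 0 of 19 past 1.5-fold on either side (median 0.17). Epithelial-mesenchymal transition genes had 8 of 18 lower and 5 higher (median -0.34), with Snai1 and Fn1 lowest, at -3.18 (-3.61 to -2.80) and -2.27 (-2.82 to -1.77), and inflammatory genes 7 of 19 lower and 3 higher (median -0.29). TGF-beta response genes differed in both directions, with 5 of 21 higher and 9 lower (median -0.35), from Inhba, an activin subunit gene, at 2.82 (2.69 to 2.94) to Id3 at -1.58 (-1.63 to -1.53).

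Of 21 interferon response genes, 20 were lower in Pik3caHR than in control basal-like cells and 0 higher (median -2.19), with Ifit3 at 0.139 against 12.2 CPM. All 7 MHC class II genes were lower (median -2.76), with H2-Eb1 at 10.5 against 196 CPM, as were 9 of 13 class I genes, with 0 higher (median -0.69). Macrophage-like cells, which express class II genes themselves, made up a larger share of the control library (26.1% against 13.1%). In these macrophages, which filled different clusters in the control and Pik3caHR libraries, the interferon median was -0.12 and the class II median -0.55. With a mitochondrial limit of 20%, at which 2 clusters stayed unnamed, 13 interferon genes were lower (median -0.99). Without cluster 7, an alternative chosen after seeing the data, 13 interferon genes were lower (median -0.99), and the class I and class II medians were -0.19 and -2.11. Both alternatives gave the same interferon values and may leave out the same cells, which was not checked, so they are not separate checks.

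Among single genes named by the rule fixed in advance, the highest in the Pik3caHR library included Saa2 and Saa1, which encode acute phase proteins, with log2 ratios of 9.48 (7.97 to 12.9) and 7.93 (7.38 to 8.60), BC023719 at 9.31 (7.43 to 15.2), and Car2, a carbonic anhydrase gene, at 6.42 (6.003 to 6.92). Sycp1, Nts and Acaa1b had 0 UMIs in control and were at least 70.3-fold, 58.9-fold and 45.2-fold higher. BC023719 differed the same way in hormone-sensing-like cells and macrophages. Saa1 did too, but at a macrophage level, 1.40% of that in basal-like cells, that free RNA gives. For Acaa1b the counts in these classes were low. It was at 2.81 CPM against 0 UMIs in control hormone-sensing-like cells, where 3 counts are 2.14 CPM, and at 1.49 against 0.272 CPM in macrophages. Nts, which encodes neurotensin, was seen in 8 of 2925 cells. The immunoglobulin genes Igha, Jchain and Igkc also passed the rule, but 1 cell held 5782 of 5808 Igha UMIs, 1952 of 1958 Jchain UMIs and 14303 of 14950 Igkc UMIs. Igha and Jchain so describe that cell, and the other 647 Igkc UMIs stand against 184 in control. The lowest were Cxcl9, a chemokine gene induced by interferon, at -8.42 (-9.34 to -7.72), Ifit3 at -6.36 (-7.78 to -5.41), Coch, with 1 UMI, at -6.30 (-12.2 to -4.35), Ifi211 at -5.87 (-6.69 to -5.22), Ifit3b, Ifi203, Rgs4, H2-Eb1, Ly6a and Ifit1, the last at -4.16 (-4.49 to -3.86).

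**Figure D2:**
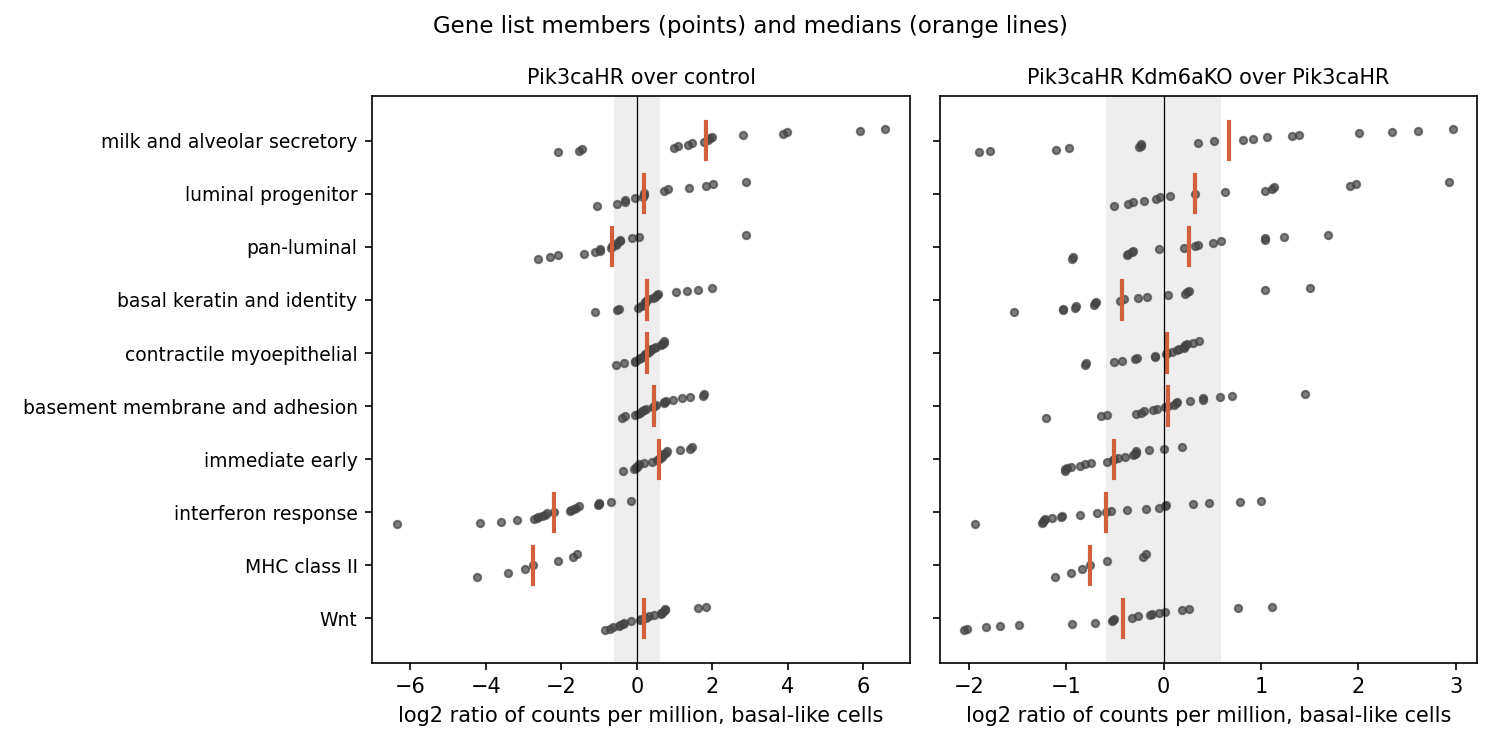
Log2 ratio of CPM in basal-like cells (x axis) for the measured members of 10 gene lists (y axis), Pik3caHR over control on the left and Pik3caHR Kdm6aKO over Pik3caHR on the right, with points for genes and lines for medians. The grey band spans ratios below 1.5-fold, and the interferon response median lies at -2.19 on the left and -0.59 on the right.

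The second comparison asked what differed when floxed Kdm6a was added to mutant Pik3ca. The Kdm6aKO library held a cluster with more basal than luminal keratin RNA but with alveolar genes among its leading genes, called mixed-keratin here by a rule set after seeing the data. It made up 10.6% (9.92 to 11.2) of the Kdm6aKO library and 0.195% (0.0843 to 0.384) of the Pik3caHR library, a ratio of 54.1 (27.4 to 126). Hormone-sensing-like cells were at 0.603% (0.451 to 0.791) against 4.63%, a ratio of 0.130 (0.0939 to 0.178), while the alveolar-like shares were alike, at 6.08% (5.59 to 6.61) against 6.22%, a ratio of 0.978 (0.841 to 1.14). Within basal-like cells, the casein genes Csn2 and Csn1s2a were higher than in the Pik3caHR library, not told apart from free RNA, and the basal identity, Wnt, immediate early and antigen presentation lists had more members lower than higher.

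The cluster came nearly all from 1 library, so library and cell type were not separated. Its name comes from the rule, not from more cells with both keratins. After thinning, both were seen in 52.0% (48.6 to 55.3) of its Kdm6aKO cells, against 79.7% of Kdm6aKO basal-like cells. Its basal keratin sum, 3260 CPM, was below that of basal-like clusters 1, 2 and 4 (10751, 6766 and 4949). Its luminal keratin sum, 1163 CPM, was nearer to theirs (1060, 837 and 755). The mixed-keratin ratio was 92.2 with the milk and luminal progenitor lists left out of the clustering, 9.45 at Leiden resolution 0.5, 16.9 at resolution 2.0 and 128 with at least 1000 genes per cell. With each library clustered alone, the Pik3caHR and control libraries had 0 such clusters and the Kdm6aKO library 2. The doublet caller removed cells from the control and Pik3caHR libraries but marked 4 barcodes (0.0447%) in the Kdm6aKO library, under the 0.5% below which nothing was removed.

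Of 18 milk and alveolar secretory genes, 9 were higher in Kdm6aKO than in Pik3caHR basal-like cells and 4 lower (median 0.67, percentile 100). Csn2, the beta-casein gene, was at 4.42 against 0.555 CPM, a log2 ratio of 2.97 (2.43 to 3.61), and Csn1s2a at 2.61 (1.61 to 3.94). Lalba, the alpha-lactalbumin gene, was at -1.78 (-3.23 to -0.63), and at 0.51 after thinning. Csn3 was at 0.51 (0.47 to 0.55). The median was -0.083 and Csn3 at -0.16 at Leiden resolution 0.5, and the median was -0.17 over all kept cells. In macrophages the milk list's median was 3.37, that of contractile genes 3.14, with 16 of 16 higher, and that of basal identity genes 2.18. Cluster 16, with 162 of these macrophages, held 1938 CPM of Krt5 and Krt14, against 109 to 786 in the other macrophage clusters, in a library with no doublets removed. Without it, an alternative chosen after seeing the data, these medians were 2.30, 1.60 and 1.62. After thinning, Csn3 was seen in 17.5% (16.5 to 18.5) of Kdm6aKO basal-like cells and 12.3% (9.66 to 15.4) of its non-epithelial cells, or 34.3% and 12.9% without thinning. For Wfdc18 these shares were 22.2% (21.1 to 23.3) and 21.8% (18.4 to 25.5), or 44.2% and 25.7% without thinning, and for Csn2 1.06% (0.803 to 1.37) and 1.65% (0.758 to 3.11), or 4.38% and 3.05%. Csn1s2a was at 1.01 CPM in basal-like cells and 3.34 CPM in macrophages, there from 12 UMIs. For these 3 genes free RNA was not told apart from expression. The Csn3 share ratio of Kdm6aKO over Pik3caHR was 1.28 (1.13 to 1.44) in basal-like and 2.86 (1.73 to 4.92) in non-epithelial cells. Its rise between these libraries was therefore not told apart from free RNA either. Median depths were 11320 UMIs in basal-like and 2783 in non-epithelial cells, and thinning left out 636 of 1181 non-epithelial cells. The non-epithelial cells included cluster 16, and these shares were not redone without it. In this library they may therefore overstate the background.

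**Figure D3:**
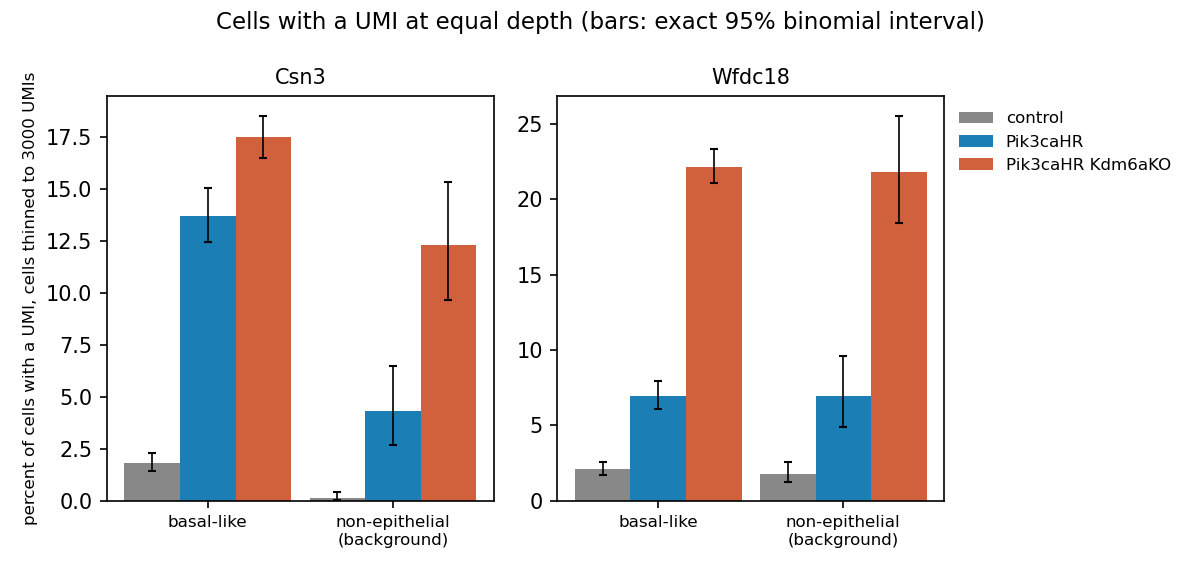
Percent of cells with at least 1 UMI (y axis) of Csn3 and Wfdc18 after thinning to 3000 UMIs, in basal-like and non-epithelial cells of the control, Pik3caHR and Pik3caHR Kdm6aKO libraries, with exact 95% binomial intervals as error bars. At this depth Csn3 lies above its share in non-epithelial cells in the basal-like cells of each library, at 1.82%, 13.7% and 17.5%, while for Wfdc18, at 2.08%, 6.96% and 22.2%, the intervals of both cell groups overlap. From the Pik3caHR to the Kdm6aKO library the Csn3 share rose by more in non-epithelial cells, from 4.29% to 12.3%.

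Luminal lists had more members higher than lower in Kdm6aKO basal-like cells, and in macrophages too, so free RNA was not told apart from expression. Of 15 luminal progenitor genes, 7 were higher and 0 lower (median 0.33), with Ltf, the lactoferrin gene, at 1.98 (1.36 to 2.69) and the receptor gene Kit at 2.94, from 44 against 4 UMIs. Of 14 hormone-sensing genes, 4 were higher and 1 lower (median 0.34). Of 16 pan-luminal genes, 5 were higher and 2 lower (median 0.27), and 2 were higher at Leiden resolution 0.5 (median -0.30) and 3 at resolution 2.0 (median 0.13), with Cldn7 at 1.69 (1.39 to 2.01) and Krt18 at -0.94 (-0.99 to -0.89). Over all kept cells these medians were -0.11, -0.79 and -0.61, in macrophages 2.29, 0.87 and 1.84, and in macrophages without cluster 16 0.73, 0.010 and 1.10. Co-detection of basal and luminal keratins was at 79.7% (78.6 to 80.8) of basal-like cells against 86.2%, and at 19.8% (16.6 to 23.4) and 3.88% of non-epithelial cells.

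Basal identity genes were lower in 8 of 18 cases and higher in 2 (median -0.43, percentile 0). Col17a1, a hemidesmosome collagen gene, was at -1.54 (-1.59 to -1.49) and Vim at -1.03 (-1.06 to -1.01), while Il17b was at 1203 against 426 CPM. Contractile genes had 2 of 19 lower and 0 higher (median 0.03). Wnt genes had 7 of 20 lower and 2 higher (median -0.42), with the ligand genes Wnt10a and Wnt6 at -2.02 (-2.12 to -1.93) and -2.05 (-2.25 to -1.86). The matrix genes Ctgf and Cyr61 of the TGF-beta response list were at -2.19 (-2.26 to -2.13) and -1.93 (-1.98 to -1.88), among 6 of 21 lower and 5 higher (median -0.17). Epithelial-mesenchymal transition genes had 8 of 19 higher and 5 lower (median 0.28). Cholesterol synthesis genes had 3 of 22 lower and 2 higher (median -0.26), glycolysis genes 3 of 16 lower and 0 higher (median -0.19) and ATF4 response genes 3 of 20 lower and 0 higher (median -0.27). Of 19 immediate early genes, 8 were lower and 0 higher (median -0.51), with Btg2 and Fos both at -1.01. Interferon response genes had 11 of 21 lower and 2 higher (median -0.59), MHC class I genes 9 of 13 lower and 0 higher (median -0.63), and class II genes 5 of 7 lower and 0 higher (median -0.75). In macrophages these medians were -1.04, with 18 of 21 lower, -0.94 and -0.71, or -1.05, -0.80 and -0.37 without cluster 16, while in hormone-sensing-like cells the interferon median was 1.00, with 8 of 15 higher. The macrophages of both libraries differed in their clusters and in depth (medians 6519 and 2407 UMIs). A different mix was not separated from a difference within macrophages. Of 19 inflammatory genes, 6 were lower and 2 higher (median -0.30), with the chemokine gene Ccl2 at -1.59 (-1.65 to -1.52) and Icam1 at -1.29 (-1.34 to -1.25).

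The highest single genes in Kdm6aKO basal-like cells were Ncan at 5.84 (3.84 to 11.7), Cnmd at 5.17 (4.43 to 6.13), BC100530, Wfdc12, Hmga2, an architectural chromatin protein gene, at 4.28 (3.29 to 5.70), Hpse2, the matrix protease gene Mmp3 at 3.85 (3.07 to 4.87), Vgf, the imprinted gene H19 at 3.29 (2.69 to 4.01) and Lrfn5. Wfdc12 came from 65 of 5686 cells and its ratio of 4.49 was -0.41 at Leiden resolution 0.5 and -0.60 at resolution 2.0. Mmp3 came from 30 cells. In control, Pik3caHR and Kdm6aKO basal-like cells, in this order, Hmga2 was at 1.21, 0.139 and 2.85 CPM and Hpse2 at 1.55, 0.159 and 3.14. Part of the ratios of Hmga2 and Hpse2 so comes from low values in the Pik3caHR library. The others of these highest genes were at 0.393 CPM or lower in control. The lowest, besides the immunoglobulin genes of the single Pik3caHR cell described above, were Pianp at -4.26 (-4.59 to -3.96), Dapk2, a death-associated kinase gene, at -4.18 (-4.72 to -3.71), Cck, the cholecystokinin gene, at -3.83 (-4.35 to -3.38), Them5 at -3.66 (-3.79 to -3.53), Acaa1b, Fndc1 and Ccdc153. Some of these were near control in Kdm6aKO basal-like cells, with the Pik3caHR library apart. In control, Pik3caHR and Kdm6aKO, in this order, Pianp was at 2, 26.8 and 1.39 CPM and Them5 at 6.98, 99.0 and 7.83. Cck was at 0.322, 8.69 and 0.604, and Fndc1 at 0.643, 14.8 and 1.31. Dapk2 (4.54, 10.2 and 0.559) and Ccdc153 (3.68, 3.43 and 0.362) were below control. Whether Them5 and Acaa1b were higher than control in other classes of the Pik3caHR library rests on few counts. In hormone-sensing-like cells they were at 1.53 and 2.81 CPM, against 0 UMIs in control, where 3 counts are 2.14 CPM. In macrophages Them5 was at 2.23 against 0.136 CPM and Acaa1b at 1.49 against 0.272 CPM. The macrophage level of Them5, 2.25% of that in basal-like cells, is one that free RNA gives. Without the basal-like cluster of low depth, Igkc and Jchain were at 0.31 and 0.79.

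The third comparison, secondary, set the Kdm6aKO library against control. Milk genes were higher in 11 of 16 cases and lower in 3 (median 1.66), interferon response genes lower in 21 of 21 (median -2.81) and MHC class II genes in 7 of 7 (median -3.71). The other described medians were 0.41 for luminal progenitor, 0.30 for hormone-sensing, -0.81 for pan-luminal, -0.11 for basal identity, 0.17 for contractile and 0.23 for basement membrane genes. They were 0.45 for fatty acid synthesis, -0.19 for immediate early, -0.27 for heat shock, -0.86 for inflammatory, 0.36 for proliferation, -0.43 for Wnt and -0.58 for TGF-beta response genes, and 12 of 13 MHC class I genes were lower. Csn2 and Csn1s1 had 0 UMIs in control basal-like cells and were at least 82.6-fold and 67.3-fold higher, with the same limit from free RNA as above. Saa2, BC023719 and Sycp1 were higher in this library too, the last at least 93.0-fold. Cxcl9, Ifi211, Cxcl10, Mill1 and AA467197 were the lowest, between -7.48 and -5.39, and BC023719 and AA467197 differed between the Pik3caHR and control libraries in macrophages too. Il17b was at 2.82 (2.79 to 2.85), Nid1 at 3.21 (3.10 to 3.32) and Inhba at 3.96 (3.85 to 4.08), while Krt18 was at -3.25 (-3.29 to -3.20) and Wnt10a at -2.65 (-2.74 to -2.56). The comparisons share libraries, so agreement between them is partly built in. Opposite signs in the first and second comparisons are partly built in too, since the Pik3caHR library is on opposite sides of them.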

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

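No paired analysis was possible because each genotype had 1 library and no test was made. Alternatives that remove the top Scrublet scores, add the mixed-keratin cluster, leave out the low-depth or interferon-led cluster or leave out the macrophage cluster with basal keratins were chosen after seeing the data. Of 105 class share ratios under alternatives 84 stayed within their counting interval, as did 74 of 108 class percentages and 147 of 170 ratios of shares of cells with a UMI, and 267 of 288 list counts stayed within 1.5-fold. Of 608 list medians 573 stayed within 0.3 of the value reported and 5 reversed. A median counted as reversed only where the value reported was over 0.3 in size. Smaller medians that changed sign, such as the pan-luminal one of Kdm6aKO over Pik3caHR, are not among these 5. Of the gene values followed, 8 of 1232 reversed for Pik3caHR over control, 23 of 1296 for Kdm6aKO over Pik3caHR and 8 of 1056 for Kdm6aKO over control, counted only where the interval reported left out 0. The cause was not tested for the values below, except that all kept cells include other cell classes. Leaving out a library was not possible, and depth limits genes with few UMIs most.

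At Leiden resolution 0.5 the basal share ratio was 1.00 for Pik3caHR over control and 0.549 for Kdm6aKO over Pik3caHR, the alveolar ratio 5.50 (Pik3caHR over control) and the mixed-keratin ratio 9.45. For Kdm6aKO over Pik3caHR 2 pan-luminal genes were higher and 1 contractile gene lower, the milk median was -0.083, Csn3 -0.16 and Wfdc12 -0.41. The Wfdc18 share ratios were 2.38 and 2.54. At resolution 2.0 the basal ratios were 1.40 and 0.838, the mixed-keratin ratio 16.9, the Csn3 and Wfdc18 share ratios 10.0 and 4.64 (Pik3caHR over control), 2 contractile genes were higher in that comparison and 3 pan-luminal genes in the other, Csn3 was -0.014 and Wfdc12 -0.60.

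The basal ratio of Kdm6aKO over Pik3caHR was 0.859 with all cells kept, 0.879 with at least 1000 genes per cell, 0.853 when clustered without the milk lists, 0.725 with each library clustered alone, 0.767 when thinned before clustering and 0.877 with a mitochondrial limit of 20%. That limit also left 2 clusters unnamed and gave a basal ratio of 1.39 for Pik3caHR over control and 13 interferon genes lower. At 1000 genes the mixed-keratin ratio was 128. Clustered alone, the cycling ratios were 6.32 and 1.68. Igkc and Jchain (Kdm6aKO over Pik3caHR) were 0.41 and 0.56 at 1000 genes, 0.35 and 0.65 at the 20% limit, and 0.31 and 0.79 without the low-depth cluster.

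Over all kept cells, for Pik3caHR over control, 22 milk and 10 hormone-sensing genes were higher, 0 pan-luminal genes lower (median 1.17) and 2 immediate early genes higher. Birc5 was 2.99, Cidea 0.77, Cldn7 2.27, Dusp1 -0.33, Foxa1 2.67, Krt18 0.22, Mcm6 0.44 and Muc15 1.12. For Kdm6aKO over Pik3caHR the milk median was -0.17, the luminal progenitor median -0.11 with 2 members higher, the hormone-sensing median -0.79 with 2 higher, 1 pan-luminal gene was higher and 19 interferon genes lower. Cldn7 was -0.37, Col3a1 0.29, Csn3 -0.23, Cxcl5 -0.24, Elf5 -0.22, Foxa1 -2.17, Ifi27l2a -1.20, Ltf -0.10, Mmp3 -1.43, Tgfbi -0.59 and Wfdc12 -2.47. For Kdm6aKO over control Cidea was 0.37, Cldn3 1.86, Dusp1 -0.70, Muc15 1.98, Procr -0.97, Tpx2 1.99 and Wnt7b 0.77.

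With list members of at least 100 UMIs, 8 milk genes were higher (Pik3caHR over control) and 1 contractile gene lower (Kdm6aKO over Pik3caHR). The mean over cells also gave 1 contractile gene lower, and Des at 0.058. Thinning to 3000 UMIs gave 8 milk and 2 hormone-sensing genes higher, 1 contractile gene lower, and Lalba at 0.51. Thinning and the limit of 100 UMIs leave out members with few UMIs, so part of these lower counts may be lost members. Without thinning, the Csn3 and Wfdc18 share ratios of Kdm6aKO over Pik3caHR were 1.05 and 2.43, with thinning to 1000 UMIs the Wfdc18 ratio was 4.13, and with the mixed-keratin cluster they were 1.61 and 4.36, with Muc15 at 0.52 over control. Without the interferon-led cluster, for Pik3caHR over control, 6 immediate early genes were higher, 13 interferon genes lower and the Wfdc18 ratio was 2.54.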

Other observations

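Of the tests below, those of proliferation genes per cell, a gland-wide interferon response, doublets, free alveolar RNA, Rosa26 linkage and mouse backgrounds were chosen only after the result was seen, and the others before. The gene patterns in hormone-sensing-like and alveolar-like cells come first. In hormone-sensing-like cells, all 22 proliferation genes were higher in the Pik3caHR library (190 cells) than in control (76 cells), with a median log2 ratio of 3.37. Median depths were 43200 and 18652 UMIs, and 21596 in the Kdm6aKO library. The genes were not spread evenly over the cells: thinned to 10000 UMIs, 66 of 169 Pik3caHR cells held at least 11 of the 22 genes and 50 held at most 2, against 2 and 51 of 62 in control. Pclaf was at 6.70 (5.40 to 8.63) and Rrm2, a ribonucleotide reductase gene, at 5.86 (4.38 to 8.21). The same 22 genes were lower in the Kdm6aKO library (52 cells) than in Pik3caHR (median -3.04), with Hmmr at 0 UMIs and at least 21.2-fold lower. Hormone-sensing genes were lower in 9 of 16 cases and higher in 3 for Pik3caHR over control (median -0.86), with Calca at -4.16 (-4.61 to -3.76). Immediate early genes were lower in 12 of 18 cases and higher in 1 (median -0.75).

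In alveolar-like cells, 11 of 23 milk genes were lower in the Kdm6aKO library (524 cells) than in Pik3caHR (255 cells) and 7 higher (median -0.55). Trf, the transferrin gene, was at -3.50 (-3.55 to -3.45), while Glycam1 was at 4.86 (4.37 to 5.44). Inflammatory genes were lower in 11 of 17 cases and higher in 1 (median -0.92). Contractile genes were higher in 14 of 16 cases and lower in 0 (median 1.76), in a library whose macrophages also held more contractile RNA (median 3.14, or 1.60 without the macrophage cluster with basal keratins).

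Interferon and MHC class II genes were lower in the basal-like cells of both mutant libraries than in control. The tables argue against RNA from macrophages, cells that a sort for green fluorescence would be meant to leave out. Read from 11 macrophage markers, it made up 0.273% of the RNA of control basal-like cells (median over the markers, which ranged from 0.186% to 55.3%), enough for 0.660% of the control level of interferon genes and 9.87% of that of class II genes (medians). A response in the whole gland of the control mouse stays open, since the interferon median for Pik3caHR over control was -1.56 in hormone-sensing-like cells but -0.12 in macrophages, and for Kdm6aKO over control -0.65 and -1.20. The macrophages filled different clusters in each library, so their values may also reflect a different mix of macrophages. The Pik3ca allele stays open too, untested, with 1 library per genotype.

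The mixed-keratin cluster came nearly all from the Kdm6aKO library. A mixture of basal-like and alveolar-like cells that gives its Wfdc18 level would be 38.0% alveolar. Of the rise over basal-like cells in that mixture, 26 alveolar and pan-luminal genes reached 5.96% (median, quartiles 0.781 and 16.0). Csn3 (104%), Muc15 (98.7%) and Ehf (80.01%) were near the mixture. The low levels of most of the 26 genes argue against doublets, and against free RNA from alveolar-like cells, as the source of the Wfdc18 level. A smaller share of alveolar RNA, which could give the small rises of those low genes, was not tested. Its median was 11587 UMIs per cell, against 11320 in basal-like and 14800 in alveolar-like cells. Loss of Kdm6a may be a cause, but with 1 library of that genotype it cannot be told apart from that mouse or library.

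Of 10453 genes with at least 10 UMIs over both libraries in each class, 28 differed by a log2 ratio of at least 1.5 between the Pik3caHR and control libraries in basal-like cells, hormone-sensing-like cells and macrophages alike, 20 higher and 8 lower. Them5, Col11a1 and Acaa1b had 0 UMIs in control hormone-sensing-like cells and were at 1.53, 3.32 and 2.81 CPM in the Pik3caHR library. Set against the bound of 3 control counts, 2.14 CPM, these genes do not pass that limit. Free RNA from basal-like cells is argued against as the whole cause, since the median macrophage level was 33.3% of the basal-like level, against 2.41% for basal genes. The margin was narrow at the lower quartile (5.31%), and 7 of the 28 lie at a level that free RNA could give. Gt(ROSA)26Sor, the gene of the Rosa26 locus itself, was among the 28. In basal-like cells, hormone-sensing-like cells and macrophages it was at -1.77, -1.56 and -1.76 for Pik3caHR over control. For Kdm6aKO over control it was at -0.01, -0.56 and 0.33, so it differed between the 2 libraries with the Pik3ca allele. Alleles linked to the Rosa26 locus were not tested for effects on the 24 genes elsewhere in the genome, and for the 3 genes within 20 Mb of it (Syn2, Wnt5b and C1s1, 0.380 expected) they stay open, since Wnt5b and C1s1 lie at that level, a condition added after their values were seen, while Syn2, at 19.7%, does not but is a single gene. Different mouse backgrounds may be a cause and cannot be told apart from the genotypes. Of the 28, 18 differed alike between the Kdm6aKO and control libraries, a count partly built in because both comparisons use the same control library.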
